A study of Homo sapiens with 4 samples.

How the data were processed

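The assay measured where an antibody against N6-methyladenosine (m6A) crosslinked to synthetic RNA. A pool of 11999 designed oligonucleotides, made by in vitro transcription, was incubated with the recombinant METTL3–METTL14 complex, the methyltransferase that writes m6A, or without it. It was then taken through miCLIP2. In this protocol reverse transcription stops at the crosslinked antibody, so that each stop marks a crosslink at single-nucleotide resolution. The labels place 2 libraries in the unmethylated group and 2 in the methylated group.

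The authors deposited raw counts per nucleotide position, without normalization, in 1 table that holds 141 positions for each oligonucleotide and library. The submitters' processing notes name FastQC 0.11.8, STAR 2.7.3a and bedtools 2.27.1. Which tool did which step, whether duplicate reads were removed and the genome build are not given in the sources used here. The table places each oligonucleotide in 1 of 4 classes. The m6A class held 1988 sequences around adenosines found methylated in HEK293T cells, a human embryonic kidney line. The unmodified class held 1500 sequences around DRACH adenosines found unmodified there (D is A, G or U, R is A or G, and H is A, C or U). The permutated class held 400 sequences in which the motif was exchanged, and 61 further sequences belonged to none of these. Most sequences were present as 3 oligonucleotides that differed only in their tag. The selected adenosine was at position 51, where every sequence of the 3 described classes held a DRACN motif.

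A site was taken as 1 position of 1 oligonucleotide, because each table line is an oligonucleotide in a library rather than a site. In tests over loci, the counts of the oligonucleotides of one sequence were summed first. Each site was assigned the 5-mer with its base in the middle. Library totals, which set the depth, were 10483825 and 12028474 in the unmethylated libraries and 13110615 and 13265092 in the methylated ones. Between the replicates of a group, oligonucleotide totals differed by far more than sampling noise (chi-square over degrees of freedom of 22.1 and 19.9), so the libraries were not merged. Amplification alone could give such a spread, so it does not show that they were separate reactions.

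Sites with at least 10 counts in at least 2 of the 4 libraries were tested with edgeR 4.0.16 (quasi-likelihood F test, trimmed mean of M values scaling, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests were two-sided. Classes of sites and gene lists with at least 20 tested sites were tested with camera and fry on voom values in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one in camera. Differences between loci and between paired sequences were tested by permutation with 100000 resamples, or by exact enumeration where it was feasible. A fold against a group with no counts was set against a floor of 3 counts per library, averaged over the group as CPM, and given as a lower bound. Standard errors of log2 fold changes were taken as the change over the square root of its F statistic. Shares have 95% Wilson intervals, ratios of the counts of a site have 95% counting intervals, and pooled ratios of permutated sequences have 95% bootstrap intervals over sequences. Wilson intervals, counting intervals and floors cover counting error only, since reads that share an origin are not independent molecules. Beyond a statement that experiments were done in duplicate, nothing in the labels says that replicates were separate reactions. P-values of the site tests and of fry therefore measure only the spread between these samples, which may be technical. Permutation p-values over loci, pairs or sequences measure the spread between those, on fold changes that average over the libraries. They do not cover the spread between libraries. Camera sets the sites of a list against the other sites.

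Gene symbols came from the overlap of the table's locus coordinates with RefSeq genes of assembly GRCh38.p14. Of 3488 loci, 98.7% lay in at least 1 gene, against 66.0% to 72.2% after the coordinates were shifted by 50000 or 500000 nt either way. Only the 3034 loci in exactly 1 gene were given a symbol, irrespective of strand. Pairing was predicted from the partition function of each 141-nt sequence with ViennaRNA 2.7.2. Summaries were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.

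Tests, gene lists and alternatives were fixed before the data were examined, as was the rule for named sites. That rule took sites past the threshold whose methylated libraries both lay on one side of both unmethylated ones: the 10 largest rises, the 5 largest falls, the called site with the highest mean CPM for each of the 18 DRACH 5-mers, and for each gene list the called site with the smallest p in at most 4 genes. Alternatives were DESeq2 1.42.0, scaling by library totals, scaling on sites outside DRACH, setting each site against the total of its oligonucleotide, no count filter, a filter of 50 counts, a threshold of 0.01, summed oligonucleotides, a replicate block, leaving out each library, the nucleotide behind the adenosine, the share without the top 1% of positions and equal weight for each sequence in the profile. Another was the sum of the adenosine and the nucleotide behind it. Splits of DRACG, of DRACH by its first or last bases and of other NNACN sites, pooled ratios, values averaged per locus, totals of oligonucleotides, and the positions and tertiles of pairing were added after seeing the data. The minimum of 5 loci of each class for the tests of single 5-mers was not fixed beforehand. The planned comparison of transcript regions was not analysed here, since no annotation of regions was used here, and no sequence carried a symbol of the planned histone list.

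The site test was tested on simulated counts for the 194723 sites, with 25 sites changed in each direction at each size. It recovered 0% of changes of 1 on the log2 scale in either direction. At 2 on the log2 scale it recovered 72.0% of rises and 12.0% of falls, at 3 it recovered 96.0% and 56.0%, and at 4 it recovered 100% and 84.0%, with 2 false calls. The set tests called 2 of 2 changed lists and 0 of 40 unchanged ones. Sites were simulated independently, without changes shared by the sites of an oligonucleotide or by its tags. The false calls found here therefore do not cover such shared changes.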

Results

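The series asked whether the sequence preference of m6A writing is intrinsic to the METTL3–METTL14 complex. It did so on 11999 synthetic RNAs that represent 3488 human loci, with antibody crosslinks counted at each nucleotide in 2 libraries of untreated RNA and 2 of RNA incubated with the complex. The unmethylated libraries held 10483825 and 12028474 counts and the methylated ones 13110615 and 13265092. Between 341 and 440 oligonucleotides had no count in a library, and the median oligonucleotide held 156 to 215 counts.

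Around the adenosine for which each sequence had been selected, methylation raised the crosslink signal at the adenosine itself more than at any other of the 20 nucleotides on either side. In the m6A class, sequences chosen around adenosines methylated in HEK293T cells, the mean signal at the adenosine was 0.489 ± 0.0410 CPM per oligonucleotide in the unmethylated libraries and 1.41 ± 0.0625 CPM in the methylated ones (SD, n = 2 each), a ratio of 2.87. The ratio was 1.55 in the class chosen around unmodified adenosines and 2.39 in the permutated class. At the other offsets of the m6A class it lay between 0.916 and 1.48, with the highest value 1 nt upstream of the adenosine. These are values per library without a test of their own.

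**Figure D1:**
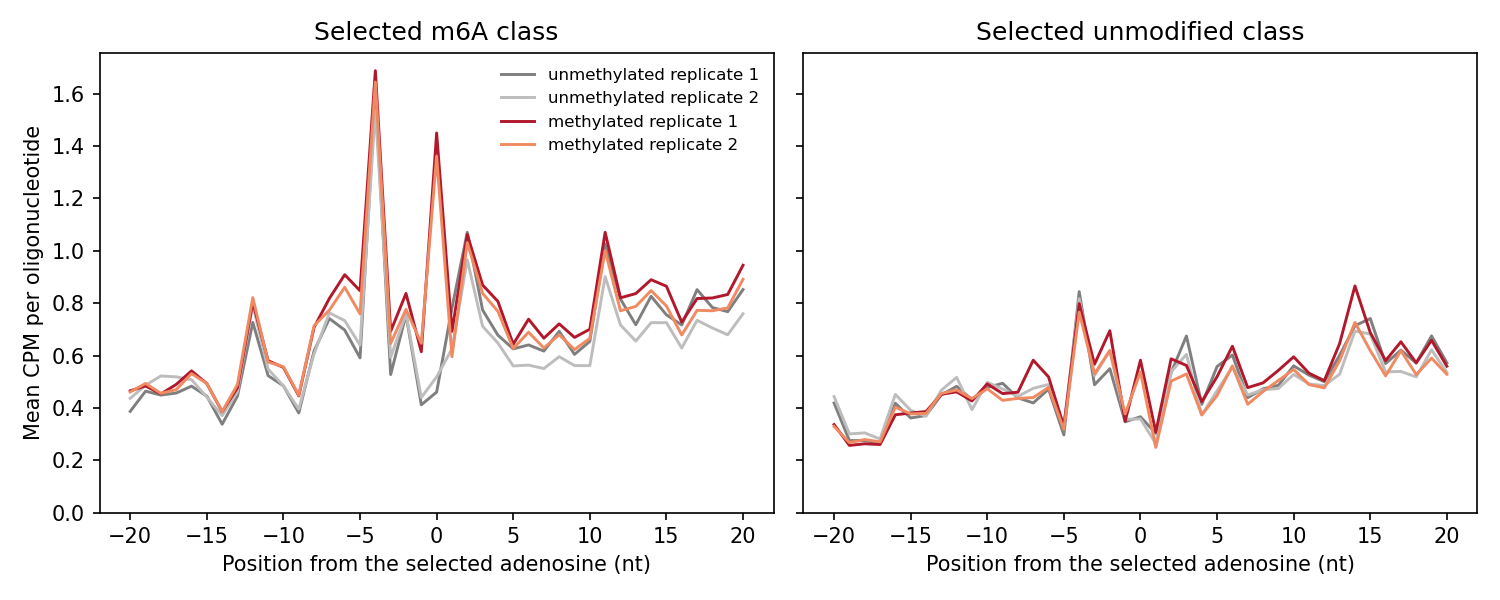
Mean CPM per oligonucleotide (y axis) at each position from the selected adenosine in nt (x axis), 1 line per library, for the m6A class (left) and the unmodified class (right). At position 0 both methylated libraries lie above both unmethylated ones, by a ratio of 2.87 in the m6A class and 1.55 in the unmodified class.

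DRACH adenosines, the consensus context of m6A, took 1.35% ± 0.0330 of all counts in the unmethylated libraries and 3.24% ± 0.0187 in the methylated ones (SD, n = 2 each), a ratio of 2.39. Single libraries gave 1.33% (95% Wilson interval 1.32 to 1.34), 1.38% (1.37 to 1.38), 3.25% (3.24 to 3.26) and 3.22% (3.21 to 3.23). DRACH adenosines made up 2.44% of all positions. The nucleotide behind the adenosine showed no such rise, with 1.38% ± 0.119 and 1.42% ± 0.0793 (SD, n = 2 each). The difference at the adenosine exceeded the spread between replicates, and its exact permutation p of 0.333 is the smallest that 2 against 2 libraries can give.

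Among single sites, DRACH adenosines rose and almost none fell. Of 5256 DRACH sites tested, 2018 were higher and 14 lower in the methylated libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and their median log2 fold change was 1.33. Over all 194723 sites, 7401 were higher and 3577 lower, so that 67.4% of the calls were rises. In simulated data with as many falls as rises, the test recovered more rises, also with sites set against oligonucleotide totals. The share of rises among calls therefore cannot show by itself that rises outnumbered falls over all sites. With each site set against the total of its oligonucleotide, 3084 sites were higher and 576 lower, 84.3% of them rises, and 1628 of these rises were at DRACH. Of the 7401 rises 2787 stayed called in this way, and of the 3577 falls 170, so that most of the 576 falls were newly called. DESeq2 called 3911 sites higher and 1902 lower. Without methylated replicate 1 there were 3956 rises and 1552 falls, of which 1345 rises were at DRACH, and without methylated replicate 2 there were 5187 and 2164.

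The 10 largest rises, each measured in 1 oligonucleotide, had no count there in either unmethylated library, and all lay at DRACH or DRACG adenosines. A GGACA in a sequence from USP19, a deubiquitinase gene, rose from 0 to 9.63 ± 0.564 CPM (SD, n = 2), at least 36-fold (edgeR adjusted p = 1.29e-07); its selected adenosine is at position 49116568 of chromosome 3. The selected GGACG of RNF126, a gene for a ubiquitin ligase (chromosome 19, position 647822), reached 7.20 ± 0.274 CPM, at least 26.9-fold. The selected GGACU of RARG, which encodes a retinoic acid receptor, rose at least 16.4-fold, with unequal methylated libraries (2.75 and 6.03 CPM). The methylated libraries of BLTP2 were also unequal (4.73 and 2.26 CPM), so that both bounds depend on single libraries. Sites in BLTP2, SH3BP4 and E4F1 rose at least 13.1-, 12.2- and 12-fold. Whole oligonucleotides rose too, in BLTP2 from a mean of 63.5 to 472 counts, in E4F1 from 330.5 to 899.5 and in USP19 from 797.5 to 2120. The bounds do not allow for this. Set against such totals, the log2 fold change of BLTP2 went from 8.42 to 7.68 (edgeR adjusted p = 0.0167), and all 10 rises stayed called. Bounds of all 10 lay between 12 and 36.

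Measured on both sides, the DRACH sites with the highest signal for their 5-mer gave graded changes. The selected GGACC of PIGU, a subunit of the enzyme that attaches GPI anchors to proteins, rose from 18.5 ± 1.91 to 387 ± 38.7 CPM (SD, n = 2 each; log2 fold change 4.37 ± 0.31 SE, edgeR adjusted p = 1.96e-08). An AGACC of URB1 rose by 4.11 ± 0.33, a GAACU of GLRX5, a mitochondrial glutaredoxin, by 3.76 ± 0.34, and an AGACA of LRFN1 by 2.11 ± 0.28 (log2 ± SE). Against the totals of their oligonucleotides, PIGU (28885.5 to 54032 counts) and GLRX5 (4012.5 to 8263.5 counts) rose by less, with log2 fold changes of 3.68 and 2.96. The selected AAACA of YWHAH, a 14-3-3 protein gene, rose by 1.62 ± 0.29 and the selected UGACU of FEN1, a flap endonuclease, by 1.43 ± 0.30. A GGACA of CIC, a transcriptional repressor, was the most abundant called GGACA but rose only by 1.09 ± 0.31 (adjusted p = 0.0391 by edgeR), a call that ended in DESeq2 (0.0510) and without 3 of the 4 libraries. Its unmethylated libraries were unequal (57.9 and 117.1 CPM), and the log2 fold change was 0.65 without the first and 1.73 without the second. FEN1 missed the threshold without methylated replicate 1 (adjusted p = 0.0522).

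The 5 largest falls all lay outside DRACN motifs, in sequences from DLX1, NCL, ATG4B, C9orf40 and NFYA, and had no count in either methylated library. The lower bounds were 6.36-, 5.23-, 5.23-, 4.92- and 4.53-fold. In DLX1, a homeobox gene, the whole oligonucleotide fell from a mean of 6370.0 to 1089.5 counts, and in NCL, which encodes nucleolin, from 2774 to 754. Set against these totals, the falls in DLX1 (log2 fold change −7.15 ± 1.31 to −6.29 ± 2.275 SE), NCL (−6.89 ± 1.37 to −6.12 ± 2.03) and NFYA (−6.67 ± 1.43 to −5.73 ± 2.87) no longer passed the threshold (edgeR adjusted p = 0.215, 0.156 and 0.441). The totals left only 2.74, 3.67 and 1.44 methylated counts to be expected per library, near the floor of 3 counts. A fall of these sites beyond that of the whole oligonucleotide was therefore not shown. Their standard errors follow from the test statistic and say nothing more. The falls in ATG4B and C9orf40 still passed the threshold against their totals (edgeR adjusted p = 0.0119 and 0.0140). Once the oligonucleotides of the sequence were summed, both missed it because the fall shrank. The log2 fold change went from −6.89 ± 1.37 to −1.89 in ATG4B (adjusted p = 0.0550 by edgeR) and from −6.79 ± 1.397 to −0.88 in C9orf40 (0.269). Summed in this way, the falls in DLX1 (−3.52), NCL (−2.06) and NFYA (−5.90) stayed called (edgeR adjusted p = 1.02e-07, 0.0221 and 4.18e-05).

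The response depended on the 5-mer, and GGAC motifs led. GGACA sites had a median log2 fold change of 2.55 (quartiles 1.30 and 4.03), with 510 of 803 higher (63.5%, 95% Wilson interval 60.1 to 66.8). GGACU had a median of 2.15 with 428 of 779 higher (54.9%, 51.4 to 58.4), and GGACC one of 1.76 with 312 of 633 higher (49.3%, 45.4 to 53.2). With sites that lacked unmethylated counts at their bounds, the medians of GGACA and GGACU were 2.44 and 2.09. GAACA (1.59), GAACC (1.56) and UAACC (1.51, 37 sites) followed, and the lowest medians were those of AGACC (0.63), UGACU (0.62) and UGACC (0.54), where 43 of 289 sites were higher.

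Grouped by the bases before the C, 1250 of 2215 DRACH sites with GGAC were higher (56.4%), 273 of 703 with GAAC (38.8%), 24.1% with UAAC, 280 of 1145 with AGAC (24.5%), 59 of 278 with AAAC (21.2%) and 15.9% of 782 with UGAC. By the last base, 45.4% of sites ending in A were higher, 36.6% of those ending in U and 33.2% of those ending in C. DRACG sites had a median of 1.62, with 369 of 827 higher. Other NNACN sites had a median of 0.28 with 322 of 4110 higher, whereas adenosines not before C (−0.06) and other bases (−0.04) had medians near 0.

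In camera, all 18 DRACH 5-mers, DRACG and other NNACN lay above the remaining sites, with adjusted p-values from 2.70e-66 for GGACA to 5.15e-04 for other NNACN. With an estimated correlation these calls held except for AAACA (adjusted p = 0.0886 with an estimated correlation) and UGACA (adjusted p = 0.0529 with an estimated correlation). Every DRACH 5-mer was also higher in fry on all 4 libraries, with adjusted p-values up to 0.0255. A fit with 1 library left out has 1 residual degree of freedom, too few for an estimated correlation or fry to decide. Whether these calls hold without a library therefore stays open at those settings. At the nucleotide behind the adenosine, no 5-mer was called by camera. Oligonucleotides of one sequence enter these counts as separate sites, so sites are not independent.

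**Figure D2:**
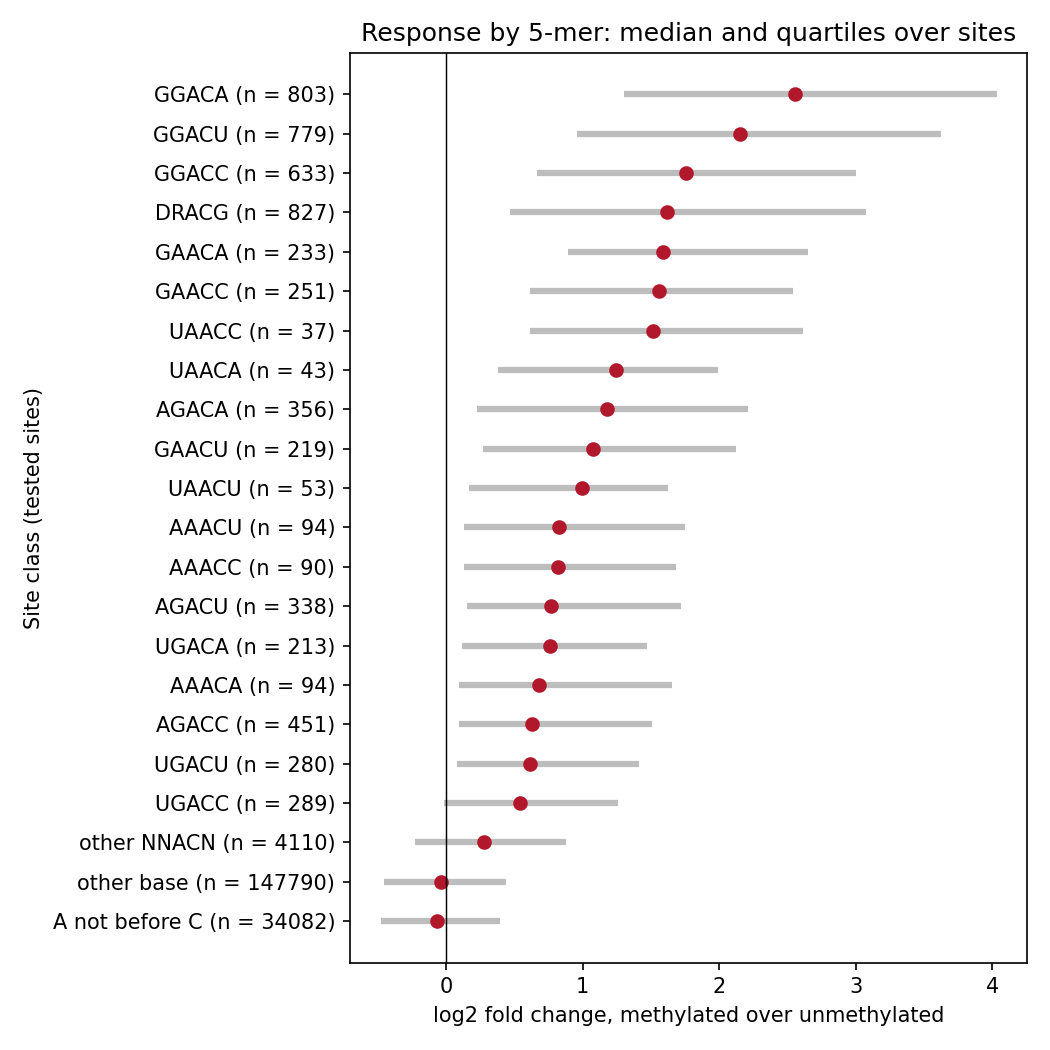
Median log2 fold change of methylated over unmethylated libraries (x axis, points) with quartiles (bars) for tested sites of each 5-mer or class (y axis, number of sites in brackets). GGACA lies highest at 2.55, and adenosines not before C and other bases lie near 0.

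Pooled over all sites of a motif without a count filter, the order at the top was GGACA (1468 ± 55.6 to 6068 ± 7.43 CPM, SD, n = 2 each; ratio 4.13), GGACG (3.44), GGACU (3.44), GGACC (3.31) and GAACA (2.93). The ratio was 2.39 over all DRACH sites, 1.43 for UGACC and 1.17 for other NNACN. UAACG fell from 279.7 ± 5.77 to 119.7 ± 4.96 CPM, a ratio of 0.428, while its 13 tested sites had a median of 1.01 with 2 higher and 2 lower.

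Adenosines methylated in HEK293T cells responded more than adenosines unmodified there. At the selected adenosine, 380 of 754 tested m6A loci were higher (50.4%, 95% Wilson interval 46.8 to 53.96) and 96 of 370 unmodified loci (25.9%, 21.7 to 30.6), by edgeR on summed oligonucleotides. The median log2 fold changes were 1.63 and 0.76, a difference of 0.87 (permutation p = 1e-05, the smallest that these permutations can give). With classes permuted within 5-mers, a difference of 0.55 remained over 1063 loci (permutation p = 7e-05). Of all counts of the class, the selected adenosine took 5.12 ± 0.450 per 1000 before and 14.3 ± 0.717 after methylation in the m6A class, and 4.85 ± 0.0594 and 7.89 ± 0.364 in the unmodified class (SD, n = 2 each).

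Of the 10 5-mers with at least 5 loci of each class, which were tested one by one, m6A loci had the higher median in 9. In 8 more 5-mers at least 1 class had under 5 loci, and there the unmodified loci had the higher median in AAACC (1.72 in 7 loci against 0.48 in 3), UAACC (1.68 in 1 against 1.19 in 2) and UAACU (1.57 in 1 against 0.61 in 6). After Benjamini-Hochberg adjustment of the permutation p-values over the 10 tests, AGACC (1.20 in 18 m6A loci against 0.43 in 54 unmodified loci) and UGACA (1.54 in 8 against 0.31 in 38) passed, each with an adjusted p of 0.0118. In GGACA the unmodified loci had the higher median, a value of 2.7 in 25 loci against 2.20 in the m6A loci (adjusted p = 0.445, permutation test). GGACC (2.25 against 1.24) and AGACA (1.13 against 0.29) missed the threshold with an adjusted p of 0.0808 each (permutation test).

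**Figure D3:**
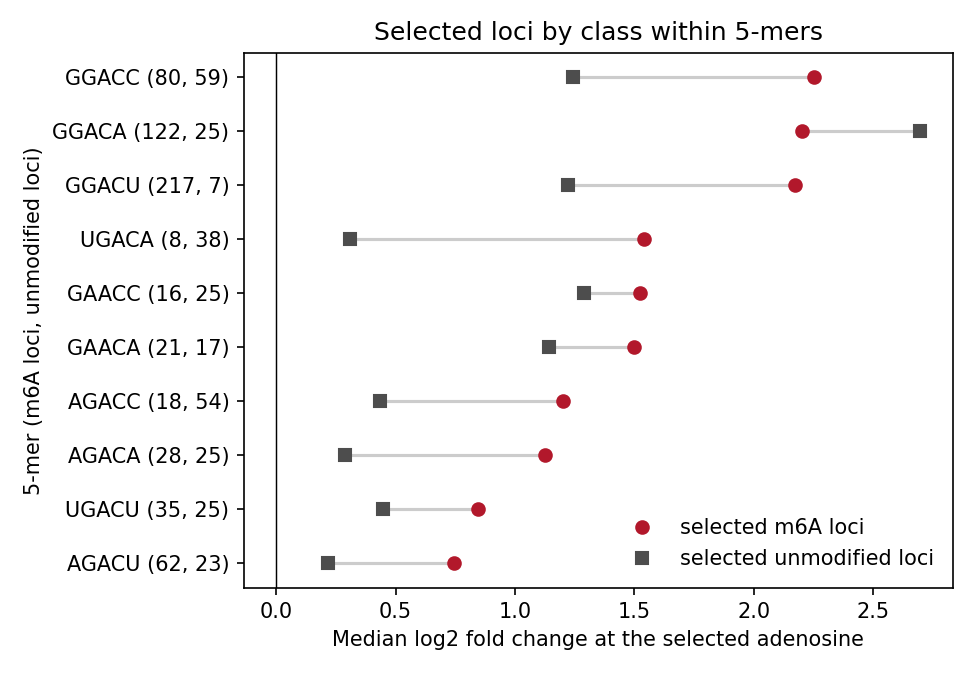
Median log2 fold change at the selected adenosine (x axis) of m6A loci (circles) and unmodified loci (squares) for each 5-mer with at least 5 loci of both classes (y axis, numbers of m6A and unmodified loci in brackets). The m6A loci lie higher in 9 of these 10 5-mers, and the unmodified loci in GGACA.

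Replacing a strong motif within its own sequence lowered the response, while the reverse exchange rested on 2 loci. Where a GGACU was replaced by a weaker motif, the log2 fold change at the selected adenosine fell by 0.91 on average (SD 1.20), with 31 of 36 pairs lower (sign-flip permutation p = 1.1e-04); averaged over the 9 original loci, it fell by 1.08 (exact permutation p = 0.0195). Where a weak motif was replaced by GGACU, GGACA or GAACU, it was higher by 0.85 in 6 pairs from 2 loci (5 of 6 higher), with an exact permutation p of 0.0625 over pairs and of 0.5 over loci, the smallest that 2 loci can give. Without a count filter the differences were −1.38 over 149 pairs and 1.65 over 64 pairs. Averaged over their 36 and 26 original loci, they were −1.35 (permutation p = 8e-05) and 1.54 (permutation p = 0.00196).

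Pooled over all 50 sequences of each kind, the selected adenosine of GGACU originals went from 3.97 ± 0.815 to 11 ± 0.884 per 1000 counts (SD, n = 2 each), a ratio of 2.78 (95% bootstrap interval over sequences 1.963 to 5.47). Their AAACC, AGACU, UGACU, GAACC and UAACC versions gave ratios of 1.61, 1.78, 1.95, 2.52 and 2.58. Their intervals were 1.32 to 1.98, 1.19 to 3.33, 1.37 to 2.85, 1.93 to 3.62 and 1.504 to 4.16, and overlapped that of the originals. Weak originals gave 2.07 (0.844 to 4.47), and their GAACU, GGACU and GGACA versions 2.76 (1.52 to 5.87), 5.87 (3.88 to 9.08) and 7.81 (4.36 to 10.498). With at least 50 counts, 12 strong-to-weak pairs were left, with a mean difference of 0.13 (permutation p = 0.732). Without unmethylated replicate 1 the weak-to-strong difference was −0.18 (exact permutation p = 0.625), and without unmethylated replicate 2 it was 2.07 (exact permutation p = 0.0312).

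**Figure D4:**
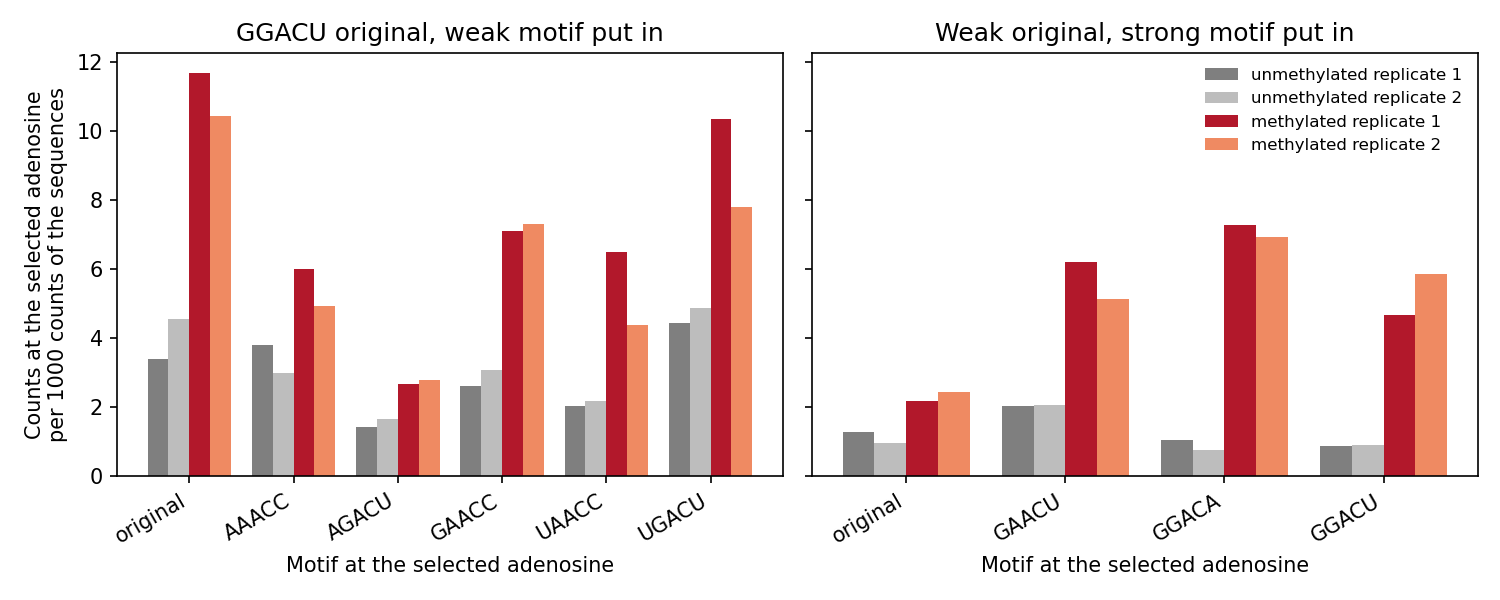
Counts at the selected adenosine per 1000 counts of the sequences (y axis), per library (bars), for originals and motif versions (x axis) of GGACU sequences (left) and of weak-motif sequences (right), 50 sequences each. The GGACA version of weak originals has a ratio of 7.81 and the AAACC version of GGACU originals one of 1.61.

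The oligonucleotides of one sequence, which differ only in their tag, gave similar responses. Across DRACH sites, log2 fold changes of pairs of tags correlated with Pearson's r between 0.716 and 0.750 (Spearman's rho 0.722 to 0.752; 995 to 1003 sites), and at the selected adenosine r lay between 0.743 and 0.752. Outside DRACN motifs r was 0.518 to 0.538. Of 706 DRACH sites tested with all 3 tags, 205 were higher in all 3 and 269 in none. Sites are not independent replicates, and the tags share the same 4 libraries.

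Of 21 DRACH sites tested in sequences from transcripts known to carry m6A, 14 were higher by edgeR (15 adjusted over the list alone), with a median log2 fold change of 3.24. They lay in DICER1 (5 of 5), SON (3 of 3), TUG1 (3 of 3) and JUN (3 of 8), while 0 of 2 DRACH sites of TAF7 were called and CTNNB1 had none to test. A GGACU of JUN, an immediate-early transcription factor gene, rose from 0.488 ± 0.0155 to 16.2 ± 0.992 CPM (SD, n = 2 each; log2 fold change 5.01 ± 0.43 SE); it was 4.385 against the total of its oligonucleotide and 3.85 with the oligonucleotides of the sequence summed. The selected GGACU of SON, a nuclear speckle protein gene, had 3 unmethylated counts and a ratio of 66 (95% counting interval 22.3 to 322.4). Its whole oligonucleotide rose from a mean of 511 to 2229.5 counts; set against this total, the log2 fold change of the site went from 5.91 to 4.09, and without unmethylated replicate 2 it was 4.90. A GGACU of DICER1, the enzyme that matures microRNAs, had 1 unmethylated count and a ratio with a 95% counting interval of 23.7 to 5326. Its oligonucleotide rose from a mean of 91 to 359.5 counts, and the log2 fold change went from 6.75 to 5.21 against this total, to 5.70 with oligonucleotides summed and to 5.83 without unmethylated replicate 2. An AGACC of the noncoding RNA TUG1 rose by 3.24 ± 0.48.

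Of the zinc finger genes, 48 of the tested DRACH sites (44.04%) were higher and 1 lower (68 and 2 adjusted over the list alone), with a median of 1.63. Examples were a selected GGACA of ZNF853 (log2 fold change 4.28 ± 0.37 SE, but 2.55 against the total of its oligonucleotide, which rose from a mean of 687 to 2720.5 counts), a GGACC of ZNF746 (3.63 ± 0.36) and a GAACA of ZNF142 (3.53 ± 0.35). Of the genes whose symbols begin with RPL or RPS, 5 of 26 DRACH sites were higher (7 adjusted over the list alone), with a median of 0.70. Of these, 4 lay in RPS6KL1 (18 tested), a kinase-like gene whose product is no ribosomal protein, and 1 in RPSA (1 unmethylated count, ratio 18.8, 95% counting interval 3.04 to 775). The RPSA call ended against oligonucleotide totals (edgeR adjusted p = 0.138), without a filter (0.0675) and with each of the 4 libraries left out in turn (0.0570 to 0.387). A site of RPL28 outside NNACN rose by 1.55 ± 0.35, a call that ended against oligonucleotide totals (adjusted p = 0.0504 by edgeR) and without unmethylated replicate 2 (0.0593) or methylated replicate 1 (0.0597). Against all other sites, the DRACH sites of these 3 lists were higher in camera, also with an estimated correlation (adjusted p = 0.0397, 0.0399 and 0.0405), as DRACH sites were in general. With an estimated correlation the model transcripts missed the threshold under library totals (adjusted p = 0.0542 in camera). Fits with 1 library left out have 1 residual degree of freedom and cannot decide these calls. Over all 588 sites of the model transcripts, the camera call (adjusted p = 0.0292) was lost (adjusted p = 0.446 with an estimated correlation).

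Sequences of the m6A machinery list had no tested DRACH site. Of their 90 tested sites, 36 were lower and 1 higher by edgeR (49 and 6 adjusted over the list alone). The list was lower in camera (adjusted p = 0.0413 with an estimated correlation, but 0.0717 under library totals). Fits with 1 library left out have 1 residual degree of freedom and cannot decide this call. All 36 falls lay in 1 gene, YTHDC1, a nuclear m6A reader, where 53 sites were tested. The YTHDC1 site with the smallest p fell from 10.6 ± 3.23 to 1.36 ± 0.203 CPM (SD, n = 2 each; log2 fold change −2.96 ± 0.39 SE). The rise lay in METTL3 (2.20 ± 0.57), a call that ended in DESeq2 (adjusted p = 0.109), without methylated replicate 1 (edgeR adjusted p = 0.308) and without unmethylated replicate 2 (0.0585). Set against the totals of their oligonucleotides, the list was not called by camera (adjusted p = 0.305) and neither site passed the threshold (log2 fold changes −1.11 and 0.87, edgeR adjusted p = 0.11 and 0.568).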

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

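The tests on whether a remaining difference passed the threshold were chosen only after the result was seen; the tests against fixed percentages were written before. The first result is here because 2 classes of loci differed under the same treatment. At one and the same 5-mer, adenosines methylated in HEK293T cells responded more to METTL3–METTL14 than adenosines unmodified there, by 0.55 in median log2 fold change (permutation within 5-mers). The explanations weighed were the count filter, GC content and predicted pairing, to be favoured if under 50% of the difference was left and disfavoured if over 80% was. Without a filter 82.8% was left (95% bootstrap interval 44.5 to 187), within strata of 5-mer and GC content 71.5% (43.9 to 118.4), and within strata of 5-mer and predicted pairing 111.1% (57.3 to 133.8), intervals too wide to settle these bounds. For the filter, the filtered and unfiltered loci were resampled independently although they overlap, which may have widened that interval. The differences left, 0.46, 0.39 and 0.61, had permutation p-values of 4.00e-05, 0.00235 and 2.00e-05. This argues against the count filter as the whole cause, and against GC content and predicted pairing only so far as tertiles capture them. Classes can still differ in either within a tertile, and a partial contribution of each explanation stays open. Sequence context beyond the 5-mer, other than these, was not tested, and loci were chosen by the study's own miCLIP2 data from cells, made with the same kind of assay.

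The second result is here because it is a signal in oligonucleotides outside the 3 described classes. Their selected position took 4.62 ± 0.573 per 1000 of their counts in the unmethylated libraries and 7.60 ± 0.937 in the methylated ones (SD, n = 2 each), and 3 of 9 tested sequences were higher there by edgeR.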

How the results depend on the processing

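Pooled motif ratios and values averaged per locus were chosen after seeing the data. On the log2 scale, the pooled ratio of 9 of the 18 DRACH 5-mers differed from the median over tested sites by more than the replicate spread. Pooling also weighs sites by their counts. Of the 46 named sites, 29 kept their direction and call under every alternative that gave a value, and none reversed; of 534 values, 42 missed the threshold, 11 of them without methylated replicate 1 and 10 when set against oligonucleotide totals. Counts of higher and lower sites were within 1.5 times those reported under library totals, scaling on sites outside DRACH, no filter, summed oligonucleotides and the replicate block (7962 and 3819). The replicate numbers did not pair the libraries (correlation of deviations −0.0697). The block ended the call of 1 named site, in RPSA (edgeR adjusted p = 0.0613). Under it all 18 DRACH 5-mers stayed called by camera with the preset correlation and 0 with an estimated one or by fry. The gene lists were at an adjusted p of 0.140 to 0.150 in camera with an estimated one. The block leaves 1 residual degree of freedom, too few for these 2 settings to decide. Counts were 3084 and 576 against oligonucleotide totals, 3911 and 1902 in DESeq2, 4357 and 2332 with 50 counts, where fewer sites were tested, and 3657 and 1345 at a threshold of 0.01. Leaving out 1 library gave 3956 to 7650 higher and 1552 to 4054 lower; a lone library was then assumed to vary like the other group. DRACH sites higher numbered 1268 in DESeq2, 936 with 50 counts and 1345 to 1895 with 1 library left out. The cause of these differences was not tested.

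With an estimated correlation 16 DRACH 5-mers stayed called on all 4 libraries. Fits with 1 library left out have 1 residual degree of freedom and cannot decide this. With 50 counts all 13 5-mers with enough sites were called by camera with the preset correlation. At the nucleotide behind the adenosine 0 of 17 were, and the medians of AAACU, AGACC, AGACU, GAACU and UGACU were −0.17, −0.10, −0.071, −0.12 and −0.21. With the adenosine and that nucleotide summed, all 18 were called by camera with the preset correlation. The medians of GGACA, GGACU and AAACA were then 1.43, 1.19 and 0.24, against 2.55, 2.15 and 0.68 at the adenosine alone. The DRACH share differed by 1.88 percentage points, by 0.0384 at the nucleotide behind and by 1.99 without the top 1% of positions. The class difference kept its direction and call under all its alternatives (0.81 to 1.26 over all loci, 0.39 to 0.73 within 5-mers). The strong-to-weak difference was 0.13 with 50 counts and −1.35 per locus without a filter. The weak-to-strong difference was 1.65 without a filter, 1.54 per locus without a filter, and −0.18 to 2.07 with 1 library left out; with 50 counts no pair was left. The mean r between tags was 0.732, and 0.816 with 50 counts. With 50 counts the DRACH sites higher numbered 8 for model transcripts, 26 for zinc finger genes and 3 for the ribosomal list, and the falls of the m6A machinery list 6, with fewer sites tested. Alternatives for transcript regions were not run. In simulated data the test recovered no change of 1 on the log2 scale.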

Other observations

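Of the tests below, those on oligonucleotide totals as the unit, scaling, chance in single oligonucleotides and selected GGACG sites were chosen after the result was seen. Outside DRACN, the medians of NNAC sites varied with their first bases, a split that was not tested and not set against oligonucleotide totals. Median log2 fold changes were 0.86 for UUAC (49 of 234 sites higher by edgeR), 0.58 for GUAC (53 of 297), 0.50 for AUAC (17 of 147) and 0.42 for UCAC (55 of 438), against 0.14 for GCAC (24 of 589) and 0.08 for CCAC (22 of 720). Over all sites outside DRACN, away from the sequence ends, 2.65% were higher, near the 4.07% of GCAC and 3.06% of CCAC. Among DRACG sites, GGACG had a median of 2.35 with 279 of 470 higher, GAACG 1.36 with 23 of 77, AGACG 0.76 with 27.9% and AAACG 0.26 with 4 of 44. With the oligonucleotides of a sequence summed, GGAC sites had medians of 1.84 at positions 3 to 35 of the sequence, 2.10 at positions 36 to 65, 2.00 at positions 66 to 95 and 2.07 at position 96 onwards.

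In a tiled sequence outside the described classes, the same GGACU took 1.67 and 1.68 per 1000 counts of its oligonucleotides in the unmethylated libraries and 24.1 and 24.2 in the methylated ones with 4 DRAC motifs present (ratio 14.4). With the other motifs removed it took 0.492 and 1.04, then 4.48 and 3.84 (ratio 5.41). Over the 5 tile pairs with at least 20 counts, the ratio with all motifs exceeded that with motifs removed in 2 pairs (14.4 against 5.41, and 14.4 against 5.51 on 2 unmethylated counts) and was lower in 3 (1.83 against 3.01, 1.43 against 1.83 and 1.29 against 1.33). GGACU adenosines of self-complementary hairpins took 0.366 and 0.135 per 1000 counts unmethylated (3 and 1 counts) and 1.47 and 1.17 methylated (8 and 8 counts).

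Of 8572 calls outside DRACN adenosines, 3558 were falls. Whole oligonucleotides changed too: of 10602 tested by their totals, 836 were higher and 464 lower by edgeR. Of the falls outside DRACN 79.9% lay in lower ones, and of the rises there 68.6% lay in higher ones. Of 3116 sequences tested with all 3 tags, 59 fell and 57 rose in all 3; the extremes, picked after their values were seen, were NFYA (mean log2 fold change −3.31), DLX1 (−2.87) and RBM23 (−2.79), and GNL3L (1.98), CCNQ (1.90) and ZC3H18 (1.87).

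Weighed for these calls were library scaling, chance in single oligonucleotides, a change of the whole oligonucleotide, and pull-down of sequences with strong motifs after methylation. A factor per library shifts all sites one way, but 41.5% of the calls outside DRACN were falls and the others rises, which argues against scaling as the whole cause. Totals of different tags correlated with a mean r of 0.660 in pairs picked because either tag held such a call. Over all pairs r was 0.560 to 0.571, which argues against chance events in single oligonucleotides as the whole cause. Setting sites against oligonucleotide totals kept 13.4% of them, against 75.9% of rises at DRACN, and their median size went from 1.92 to 0.84 on the log2 scale with a median standard error of 0.43 and 0.40, so a change of the whole oligonucleotide is a candidate explanation for much of it. Counts outside DRACN changed with the number of GGAC motifs of the sequence (Spearman's rho 0.242, permutation p = 1e-05, the smallest possible, adjusted p = 1.75e-05 over 7 sequence features), from a median log2 fold change of −0.08 with 0 motifs to 0.16 with 3 and 0.15 with 4 or more, so stronger pull-down of methylated sequences may contribute. The rho was 0.139 for DRAC motifs, 0.0958 for U, −0.0808 for A and 0.0620 for C content, all past the threshold, so other sequence features stay open. Only the DRACN adenosines themselves were left out of these counts. Nucleotides beside them stayed in, and 1 nt upstream of the selected adenosine the ratio in the m6A class was 1.48. The relation to GGAC motifs therefore cannot separate pull-down from signal next to methylated adenosines. Pull-down leaves the falls in DLX1 and NFYA open, since medians by motif number are far smaller.

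The high response of DRACG was weighed as the work of 1 of its 5-mers and of the choice of sites. DRACG sites without GGACG had a median 33.4% of that of GGACG (95% bootstrap interval 26.99 to 44.5), so that GGACG may carry the class. GGACG away from the selected adenosine had a median 70.6% of that at selected ones (55.5 to 83.3; medians 2.18 in 354 sites and 3.09), which leaves open whether the choice of sites as methylated in cells contributes. Both intervals resample sites and take the oligonucleotides of one sequence as separate sites, so they may be too narrow.

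A hypothesis that unpaired motifs respond more gave no clear result. Within 5-mers, the log2 fold change had no clear relation to the predicted unpaired probability over 4235 sites (Spearman's rho 0.0273, 95% interval −0.00277 to 0.0574, permutation p = 0.0760). Of 4 cores tested apart, without adjustment for the 4 tests, GGAC had a rho of −0.0155 (permutation p = 0.526), GAAC one of 0.0334 (p = 0.428), AGAC one of 0.0752 (p = 0.0246) and UGAC one of 0.0884 (p = 0.0235). Predictions used the sequence without its tag and linker.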
